A study of Homo sapiens with 9 samples.

How the data were processed

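RNA was sequenced from 9 libraries of human macrophages, 3 each of blood macrophages, MSC-educated macrophages and BM macrophages, and each library was placed in its group by its labels. Per the labels' protocols, macrophages were grown from blood mononuclear cells isolated on day 0, given fresh medium or MSCs of passage 4 or 5 on day 7 at 10 macrophages to 1 MSC, and collected on day 10 by CD14 and sorted again on CD14. How the BM macrophages were grown was given only by the file header, which calls them derived from CD14-positive BM cells. Nothing said which libraries shared a donor, a culture or a sequencing run.

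The authors deposited 1 table with a log2(FPKM + 1) value per gene and library, per the file headers. Trimmomatic 0.32, a tool that trims adapters and poor bases from reads, and the genome build hg19 were named in the submitters' processing notes. The aligner, the program that estimated FPKM, the annotation release, the strand setting and any filter are not given in the sources used here. FPKM divides the fragments of a gene by its length and by the mapped fragments of the library, so a class of RNA that takes a larger share in 1 library lowers the values of all other genes there. Small RNA genes took 40.2% of summed FPKM in MSC-educated replicate 3 and 15.1% to 21.5% in the other libraries. Short genes hold a smaller share of fragments than of summed FPKM, so these shares do not show how far other genes were lowered. Because such a difference in composition can matter, the comparisons were repeated under 5 other scalings.

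The table held 57501 entries, of which 107 repeated an earlier gene identifier. Of the identifiers, 47030 (81.8%) matched a current symbol by Ensembl gene identifier, and other genes keep the name in the table. Gene types and lengths came from the GENCODE annotation of a later genome build, matched by identifier, and none of its coordinates were used. Coordinates are those of the table, on hg19, shown counting from 1. The table's starts were taken to count from 0 because, for 4189 of 4675 small RNA genes (89.6%), end minus start equalled the annotated length. Before any test, 514 entries (XIST, TSIX and Y-linked genes) were left out. All 37 mitochondrial genes were listed at 0 in every library. Of the tested genes, 116, 9 of them protein-coding, were listed at 0 in a library while another of the same group had a log2 value of 4 or more. THUMPD1, for example, was listed at 0 in blood replicate 1 and at 4.58 to 4.83 in the other 8 libraries. A value of 0 can therefore be a failed estimate, and genes with such values are given per library. No column of per-sample values was left unmapped.

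Total reads were not given. Where fragments are counted whole, the lowest values of genes of equal length fall on steps worth 1 fragment, and the lowest step of genes 107 nucleotides long, the most frequent length, was compared between libraries. It rested on 5 to 18 genes per library, of which 60.0% to 100% lay within 5% of the step, so the relative depths are crude. By that measure the BM libraries were the shallowest (0.35, 0.36 and 0.53 of the deepest), so low genes are least certain there. No interval for counting error can be given without counts.

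The test planned for count data was not used because the values were log2 FPKM, and the plan for normalized values applied instead. Genes with an FPKM of 1 or more in at least 3 libraries were tested, 12918 in all, of which 10781 were protein-coding. limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) fitted a mean per group over all 9 libraries to the deposited values, with a variance trend and robust empirical Bayes moderation, 2-sided. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and counts are also given at an absolute log2 fold change of 1 or more. Fold changes are on the log2(FPKM + 1) scale, with a pseudocount of 1, and understate the change of low genes. An exact test of 3 libraries against 3 cannot give a p under 0.1, which is why the moderated test across genes was used.

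Sets of 25 gene lists, written before the data were examined, were tested with fry of limma, which asks whether the members move on balance in 1 direction and does not compare a list with other genes. The 19 lists with at least 5 tested members were adjusted together within a comparison. Each call is given with the adjusted p of camera with an estimated correlation between genes, under which no list passed in any comparison (0 of 19, with 5, 3 and 0 lists at an unadjusted p under 0.05). Numbers "adjusted over the list alone" use the same p-values adjusted within the list.

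The genes named were fixed by a rule written before the data were examined. In each comparison these were the 8 largest rises and 8 largest falls among genes that passed, did not overlap between the groups and averaged an FPKM of 5 or more in the higher group, up to 3 members with the smallest adjusted p of each list that moved, and a panel of 15 genes whatever their result. Immunoglobulin and T cell receptor segments and genes that are commonly deleted in some people were left out of the largest changes. Other genes are named as chosen after their values were seen, and these were not followed through the alternatives. Some genes are not reported here.

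Alternatives were the 5 scalings (quantile, upper-quartile, median-ratio, the macrophage identity list, and protein-coding genes alone), no expression filter, a minimum of FPKM 5, pseudocounts of 0.5 and 0.1, genes with a 0 beside a high value left out, only the libraries of the compared groups, the replicate number as a block, camera in place of fry, and leaving out each of the 9 libraries. The test was tried on simulated data with 50 genes changed at each size in 12918 tested genes. The changed genes had a mean log2 value above 2, and each gene had the same normal spread in every group. Recovery of lower genes, or with a spread that differs between groups, was therefore not measured. For MSC-educated against blood macrophages it recovered 38%, 80%, 94% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale with 10 false calls, and for MSC-educated against BM macrophages 36%, 86%, 94% and 100% with 8. The simulated comparison of BM with blood macrophages held no change and gave 0 calls.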

Results

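RNA sequencing compared macrophages that had been cultured with mesenchymal stromal cells (MSCs) with macrophages that had not. MSCs are adherent connective tissue cells that can be grown from bone marrow (BM). Macrophages were isolated from peripheral blood mononuclear cells on day 0. On day 7 they received fresh medium (blood macrophages) or BM MSCs (MSC-educated macrophages), with 10 macrophages for each MSC, and CD14-positive cells were collected and sorted again on CD14 on day 10. The other group, BM macrophages, was described in the file header as derived from CD14-positive BM cells. Each group held 3 libraries, 9 in all. The values were log2(FPKM + 1), where FPKM is fragments per kilobase of transcript, scaled to the mapped fragments. All means are on that scale and are given as mean ± SD with n = 3 libraries per group.

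Read totals per library were not given, so depth could only be compared. Between 18522 and 21895 genes were listed above 0 in a library, and summed FPKM ran from 553890 to 650163. Steps in the lowest values of genes 107 nucleotides long, the most frequent length, gave a crude relative depth, set to 1 in the deepest library, of 0.35, 0.36 and 0.53 in BM replicates 1, 2 and 3. In the other libraries it was 0.61 or more. Small RNA genes took 40.2% of summed FPKM in MSC-educated replicate 3 and 15.1% to 21.5% in the others. Nothing in the labels said whether the libraries came from separate donors or cultures, so the p-values measure the spread between these libraries, which may be technical.

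The macrophage identity markers were expressed in all 9 libraries. CD14 (chromosome 5, 140011313 to 140013286, build hg19), the receptor on which the cells were sorted, was 7.18 ± 0.23 in blood, 7.28 ± 0.67 in MSC-educated and 6.89 ± 0.23 in BM macrophages. None of the 3 CD14 differences passed the test (limma adjusted p = 0.901, 0.588 and 0.649 for MSC-educated against blood, MSC-educated against BM and BM against blood). The mean of the 18 identity markers was 7.23 to 7.54 in the blood libraries and 6.87 to 7.15 in the BM libraries. In MSC-educated replicates 1, 2 and 3 it was 7.13, 7.55 and 6.51. Across genes, which are not independent replicates, library pairs of the same group correlated at 0.912 to 0.948 and pairs from different groups at 0.831 to 0.927. The first principal component held 31.3% of the variance and the second 21.6%.

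**Figure D1:**
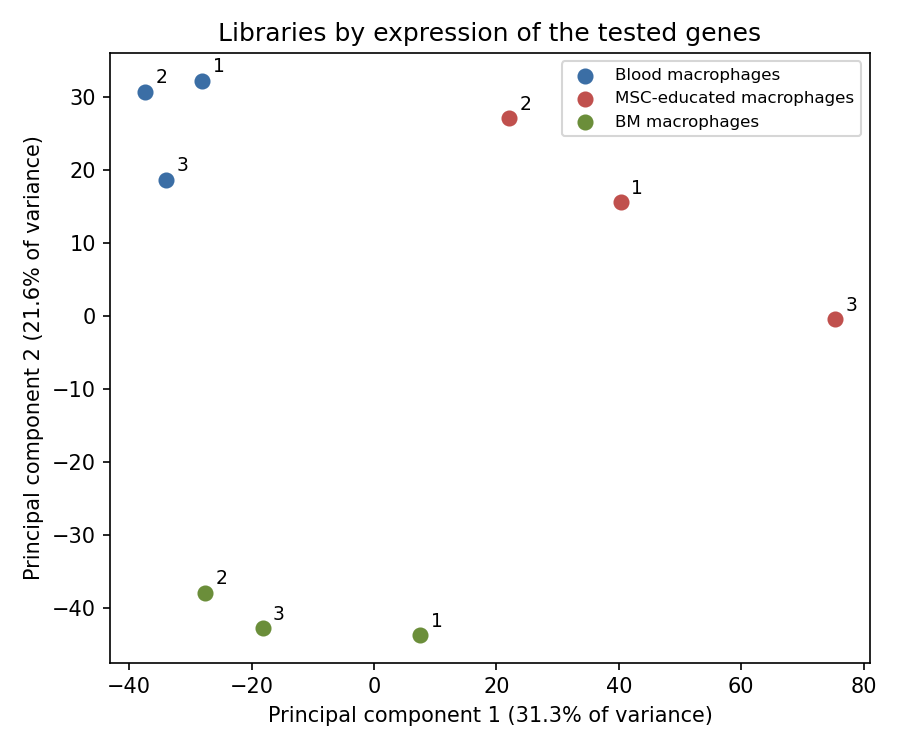
Principal component scores of the 9 libraries over the tested genes, with 1 point per library, coloured by group and numbered by replicate. The 3 MSC-educated libraries lie at 22.1 or more on component 1, above all blood and BM libraries, and the 3 BM libraries lie at -37.9 or below on component 2.

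The first comparison asked what followed 3 days of contact with MSCs, with blood macrophages given fresh medium as the control. Collagen genes were among the largest rises. COL1A2 and COL1A1, the chains of type I collagen, went from 0.76 ± 0.12 to 8.72 ± 1.01 and from 0.55 ± 0.21 to 8.23 ± 1.08 (log2 fold changes 7.95 ± 0.94 SE and 7.68 ± 0.88 SE, limma adjusted p = 0.00598 and 0.00544). SERPINE2, a secreted serine protease inhibitor, rose by 7.38 (SE 0.48, limma adjusted p = 1.02e-04). The proteoglycan genes DCN and LUM rose by 6.75 and 5.86, and COL3A1, EFEMP1, CCDC80 and COL12A1 rose by 5.79 to 6.73. COL1A1 lies on chromosome 17 at 48260650 to 48278993, COL1A2 on chromosome 7 at 94023873 to 94060544, SERPINE2 on chromosome 2 at 224839829 to 224904036 and DCN on chromosome 12 at 91539025 to 91576900 (hg19, whole genes). Of the mesenchymal stromal markers, a list fixed before the data were examined, 24 of 26 tested members were higher and none lower, and all 26 were higher when adjusted over the list alone. COL6A2 and IGFBP5 did not pass over all genes. The list had a median log2 fold change of 4.52 and moved up (fry p = 5.85e-04, adjusted p = 0.0111), with adjusted p = 0.0896 with an estimated correlation. FN1, the gene of fibronectin, was 3.86 ± 0.42 in blood and 10.72 ± 1.32 in MSC-educated macrophages (limma adjusted p = 0.0195).

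The level of the stromal markers differed between MSC-educated libraries. Their mean was 5.60, 4.63 and 6.07 in MSC-educated replicates 1, 2 and 3 and 0.50 to 0.75 in the blood libraries. Of the raised genes outside the list that averaged under 1 FPKM in blood macrophages, 171 of 247 followed the same order of libraries, 3 above 1 above 2. The calls of 9 of the 10 genes named in the stromal account held in every fit that left out a library. The FN1 call was lost without any blood library or MSC-educated replicate 1 or 3 (limma adjusted p = 0.0586 to 0.130). The stromal list lost its call without blood replicate 2 (adjusted p = 0.0572) or 3 (0.0598).

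**Figure D2:**
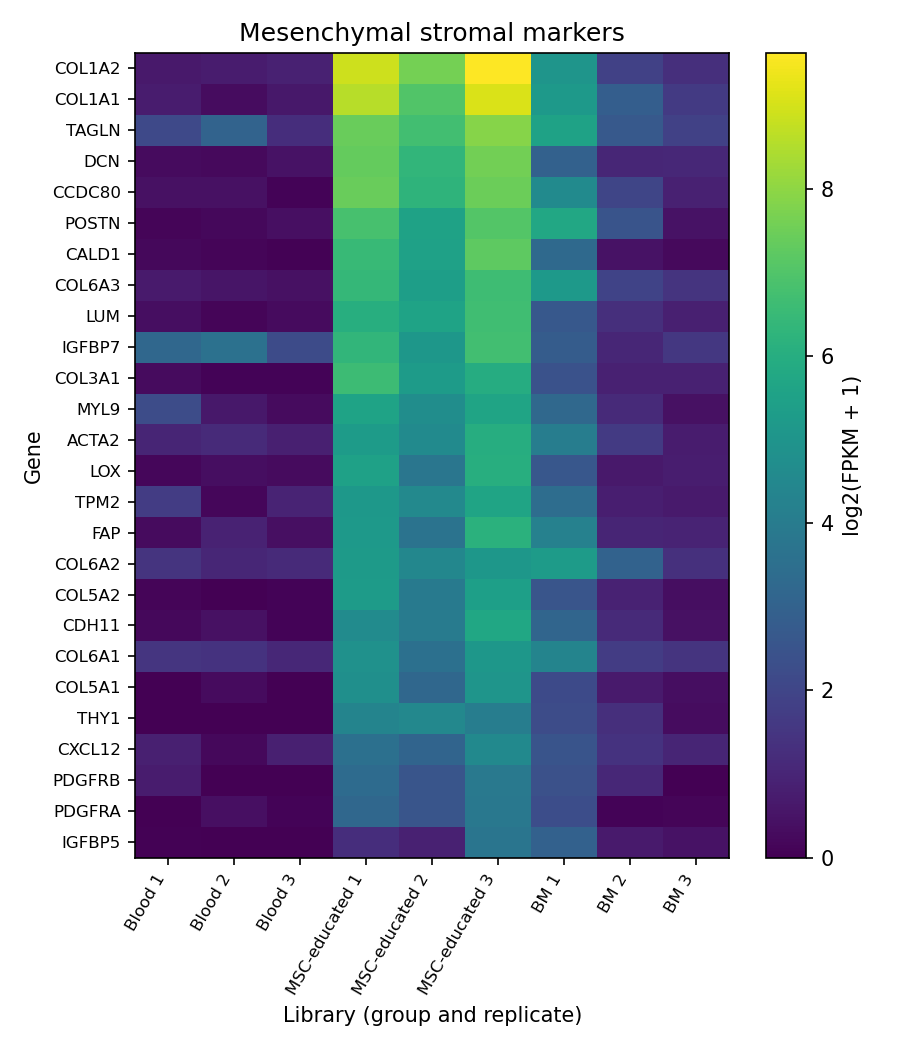
Expression of the 26 mesenchymal stromal markers (one line per gene) in each of the 9 libraries (columns, by group and replicate), with colour showing log2(FPKM + 1). Values are high in the 3 MSC-educated libraries (list means 5.60, 4.63 and 6.07), low in the blood libraries, and intermediate in BM replicate 1 (list mean 3.58).

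Single cytokine, growth factor and scavenger receptor genes also rose in MSC-educated macrophages, 1 of 7, 3 of 16 and 3 of 17 tested members. IL6, an inflammatory cytokine, was 4.13, 2.38 and 3.48 in MSC-educated replicates 1 to 3 and 0.38, 0.36 and 0.22 in the blood libraries (limma adjusted p = 0.00522). Like the stromal markers it was lowest in MSC-educated replicate 2, but it was highest in replicate 1 and so did not follow their full order. Whether the IL6 transcripts came from macrophages or from MSCs was not tested. IL6 was the only 1 of 7 tested proinflammatory cytokines to pass over all genes, and 3 were higher when adjusted over the list alone. The list moved up (fry p = 0.00751, adjusted p = 0.0285) with a median log2 fold change of 0.03, and had adjusted p = 0.145 with an estimated correlation. That median was -0.13 after quantile normalization and 0.13 to 0.28 under the 4 other scalings, and 0.05 and 0.10 with pseudocounts of 0.5 and 0.1. It was 0.69, 1.07 and -0.17 without blood replicates 1, 2 and 3, 0.12 and 0.09 without MSC-educated replicates 1 and 3, and 0.59 without BM replicate 2 or 3. IL1B (2.62 ± 0.16 and 3.77 ± 0.54) and OSM (1.19 ± 0.24 and 2.68 ± 0.77) did not pass (limma adjusted p = 0.0610 and 0.0673), and TNF was 1.16 ± 0.46 and 1.19 ± 0.21 (0.974). IL1B passed under all 5 other scalings (limma adjusted p = 0.0164 to 0.0392). OSM passed under each of them but quantile normalization (0.0132 to 0.0329) and without MSC-educated replicate 3 (0.0367). IL6 kept its call in the 6 left-out fits that tested it. The filter removed it when an MSC-educated library was left out. The cytokine list call was lost without any of the 6 libraries of the 2 groups or without BM replicate 1 (adjusted p = 0.0510 to 0.720).

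Of 16 tested growth factor and repair genes, VEGFA, FGF2 and THBS1 rose and GDF15 fell. Over the list alone, 4 were higher and 2 lower. THBS1, which encodes the matrix protein thrombospondin 1, went from 2.76 ± 1.07 to 9.34 ± 1.03 (limma adjusted p = 0.00714). VEGFA, the main growth factor for blood vessels, went from 3.58 ± 0.46 to 5.51 ± 0.64 (limma adjusted p = 0.0300). FGF2 was 2.80, 1.42 and 3.32 in MSC-educated replicates 1 to 3 and listed at 0.02, 0 and 0.02 in the blood libraries (limma adjusted p = 0.0117). GDF15, a stress-induced secreted factor, fell by 1.51 (SE 0.31, limma adjusted p = 0.0290). The list moved up (fry p = 0.00433, adjusted p = 0.0274, median 0.27), with adjusted p = 0.0896 with an estimated correlation. The median was 0.42 to 0.55 under the 5 other scalings, 0.46 without blood replicate 1 and 0.07 without MSC-educated replicate 2. Of 17 tested scavenger and phagocytic receptor genes, MERTK, AXL and GAS6 rose and none fell over all genes. Over the list alone, 8 were higher and 1 lower. GAS6 encodes a ligand that bridges apoptotic cells to the receptors MERTK and AXL. GAS6 rose by 3.44 (SE 0.42, limma adjusted p = 0.00264), AXL by 2.81 (SE 0.55, limma adjusted p = 0.0224, and 4.74 with a pseudocount of 0.1) and MERTK by 1.39 (SE 0.30, limma adjusted p = 0.0341). MERTK was already high in blood macrophages (4.54 ± 0.31), whereas GAS6 (0.75 ± 0.19) and AXL (0.31 ± 0.28) were near the floor there. GAS6, AXL, FGF2, THBS1, VEGFA and FN1 followed the library order of the stromal markers. The list moved up (fry p = 0.00378, adjusted p = 0.0274, median 1.20), with adjusted p = 0.0896 with an estimated correlation, and its median was 0.78 without blood replicate 2 and 0.73 without MSC-educated replicate 3.

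GAS6 kept its call in every fit that left out a library. The calls of VEGFA, AXL and GDF15 were each lost without blood replicate 1, 2 or 3 or without MSC-educated replicate 1 or 3 (limma adjusted p = 0.0508 to 0.158). MERTK lost its call without any of the 6 libraries of the 2 groups (0.0525 to 0.147). THBS1 lost it without MSC-educated replicate 1 (0.0557) or 3 (0.0633), and FGF2 without blood replicate 3 (0.0517). The growth factor list call was lost without any blood library or MSC-educated replicate 1 or 2 (adjusted p = 0.0771 to 0.189), and the scavenger list call without blood replicate 2 or 3 or MSC-educated replicate 1 or 2 (0.0825 to 0.110).

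Genes that fell in MSC-educated macrophages were fewer and changed less. APOBEC3A, a cytidine deaminase of innate immunity whose close paralog APOBEC3B may share reads (chromosome 22, 39348746 to 39359188, hg19), fell by 3.75 (SE 0.57, limma adjusted p = 0.00790), from 4.92 ± 0.86 to 1.16 ± 0.72. IL2RG, the common gamma chain of several cytokine receptors, fell by 2.66, PDE6G by 2.39, the integrin gene ITGAL by 2.28 and HSD11B1, whose enzyme regenerates cortisol from cortisone, by 2.27 (limma adjusted p = 0.00648, 0.00636, 0.00590 and 0.00644). CHI3L1, a secreted chitinase-like protein, fell from 8.73 ± 0.59 to 6.26 ± 0.48 (limma adjusted p = 0.0305). AC064836.1, for which no gene type was matched, and the processed pseudogene ENSG00000256664 were lower by 2.32 and 2.21 (limma adjusted p = 0.0225 and 0.0322). Reads of a pseudogene can be shared with its partners, so the value of ENSG00000256664 is uncertain. The osteoclast markers moved down (fry p = 0.00704, adjusted p = 0.0285, median -1.15), with adjusted p = 0.231 with an estimated correlation, and had a median of -0.67 without MSC-educated replicate 3. Of 7 tested members, only SIGLEC15, a receptor in osteoclast fusion, fell over all genes, by 1.89 (SE 0.33, limma adjusted p = 0.0126). Over the list alone, 4 were lower. ATP6V0D2 and OSCAR had log2 fold changes of -1.15 and -0.71 and did not pass (limma adjusted p = 0.0693 and 0.185), though ATP6V0D2 passed among protein-coding genes alone (0.0385).

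IL2RG, PDE6G, ITGAL and HSD11B1 kept their calls in every fit that left out a library. APOBEC3A lost its call without MSC-educated replicate 3 (limma adjusted p = 0.0573). SIGLEC15 lost its call without blood replicate 1 (0.0525) or 3 (0.0614) or MSC-educated replicate 1 (0.0800) or 3 (0.0724). CHI3L1 and ENSG00000256664 lost theirs without any of the 6 libraries of the 2 groups (0.0581 to 0.192), and AC064836.1 without blood replicate 2 or 3 or any MSC-educated library (0.0526 to 0.108). The osteoclast list call was lost without any blood library, MSC-educated replicate 2 or BM replicate 3 (adjusted p = 0.0525 to 0.110).

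Genes of immune regulation gave no directional change. Of 18 tested members, PTGS2 and NT5E were higher and CD274 lower, and the list had a median of -0.14 (0.03 to 0.12 under 4 other scalings), a mean of -0.01 and fry adjusted p = 0.897, with camera pointing up. NT5E, the ectoenzyme CD73 that is also a surface marker of MSCs, went from 0.60 ± 0.31 to 3.32 ± 1.01 (limma adjusted p = 0.0296) and followed the library order of the stromal markers. It lost its call without any blood library or MSC-educated replicate 1 or 3 (0.0737 to 0.139). CD274, the checkpoint ligand PD-L1, was 3.00 ± 0.34 and 1.49 ± 0.72 (limma adjusted p = 0.0421). It lost its call in 8 of the 9 left-out fits (0.0506 to 0.167), all but the fit without MSC-educated replicate 2, and in 7 of the 12 other alternatives. IL10 was 2.86 ± 0.63 and 3.66 ± 0.45, TGFB1 4.35 ± 0.12 and 3.91 ± 0.61, TNFAIP6 1.14 ± 0.30 and 1.61 ± 0.42, and CD163 6.59 ± 0.52 and 6.78 ± 0.23 in blood and MSC-educated macrophages, and none of these passed (limma adjusted p = 0.359, 0.481, 0.448 and 0.776). The mannose receptor gene MRC1 was 4.12 ± 0.82 and 5.54 ± 0.28 (limma adjusted p = 0.0712) and passed without blood replicate 1 (0.0152) and under the 4 other scalings that tested it (0.0250 to 0.0366). IDO1, ARG1 and IL12B did not reach the expression filter.

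The other lists gave no directional change on the deposited scale, adjusted over 19 tested lists. Members named in this account outside the fixed rule were chosen after their values were seen. Among alternative activation genes (15 tested, fry adjusted p = 0.759) only VSIG4 was higher, and among inflammatory chemokines (10 tested, 0.897) only CCL4 was lower, whose near-identical copies may share its reads. CFP was lower among 14 complement genes (0.949), where the median (0.01) and mean (0.13) lay above 0 and fry, unlike camera, pointed down. SLC2A1, BNIP3 and CA12 were higher among 19 glycolysis and hypoxia genes (0.0539). That list was called under all 5 other scalings (adjusted p = 0.00340 to 0.0207) and without MSC-educated replicate 3 (0.0143), BM replicate 1 (0.0475) or BM replicate 2 (0.0365). CEBPA was lower among the 18 macrophage identity markers (0.468), MCM6 lower among 17 cell cycle genes (0.665), and FCGR3B, which has the close copy FCGR3A, higher among 8 granulocyte markers (0.897), where the median was -0.05 and the mean 0.25. No member passed over all genes among 18 interferon response genes (fry adjusted p = 0.201), 15 antigen presentation genes (0.244), 13 matrix proteases (0.244), 14 lipid handling genes (0.468), 18 cholesterol synthesis genes (0.209) or 15 immediate early and stress genes (0.897). LIPA of the lipid list was listed at 10.32, 9.96 and 0 in blood and at 0, 9.59 and 0 in MSC-educated replicates 1 to 3, zeros that can be failed estimates. The matrix protease list was called under all 5 other scalings (adjusted p = 0.0129 to 0.0484) and without MSC-educated replicate 3 (0.0460), and the cholesterol synthesis list, downwards, after scaling to the macrophage identity list (0.0484). With the replicate number as a block the interferon response list was called, downwards (fry adjusted p = 0.0410). Too few members were tested of the T and NK cell (4), B cell (1), erythroid (0), platelet (3), stem and progenitor (1) and dendritic cell (2) markers, and none of those tested passed.

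In all, 426 of 12918 tested genes differed between MSC-educated and blood macrophages, 350 higher and 76 lower (limma with Benjamini-Hochberg adjustment). With an absolute log2 fold change of 1 or more there were 346 higher and 67 lower, and 2073 genes had an unadjusted p under 0.05. In 22.7% of tested genes all 3 libraries of one group lay above all 3 of the other, against 10% by chance. The count was 244, 179 and 154 without blood replicates 1, 2 and 3, and 76 and 99 without MSC-educated replicates 1 and 3. It was 253 with no expression filter and 178 with a stricter filter. With no expression filter AXL, MERTK, VEGFA, GDF15, NT5E, CD274, CHI3L1, AC064836.1 and ENSG00000256664 lost their calls (limma adjusted p = 0.0770 to 0.112), and so did the cytokine, growth factor, scavenger and osteoclast lists (adjusted p = 0.0819 to 0.0980). Scaling to the macrophage identity list ended the calls of FN1, AXL, VEGFA, GDF15, NT5E, CD274, AC064836.1 and ENSG00000256664 (0.0504 to 0.221). AC064836.1 and ENSG00000256664 also lost theirs under upper-quartile and median-ratio scaling (0.0609 to 0.0687), AC064836.1 after quantile normalization (0.0785), ENSG00000256664 with a pseudocount of 0.1 (0.121) and NT5E with the stricter filter (0.0630). The stricter filter ended the growth factor, scavenger and osteoclast list calls (0.0544 to 0.0676), and a fit of only the 2 groups compared ended these and the cytokine call (0.0614 to 0.0910). The median log2 fold change of all tested genes was -0.15 and ran from -0.09 to 0.08 under 5 other scalings.

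**Figure D3:**
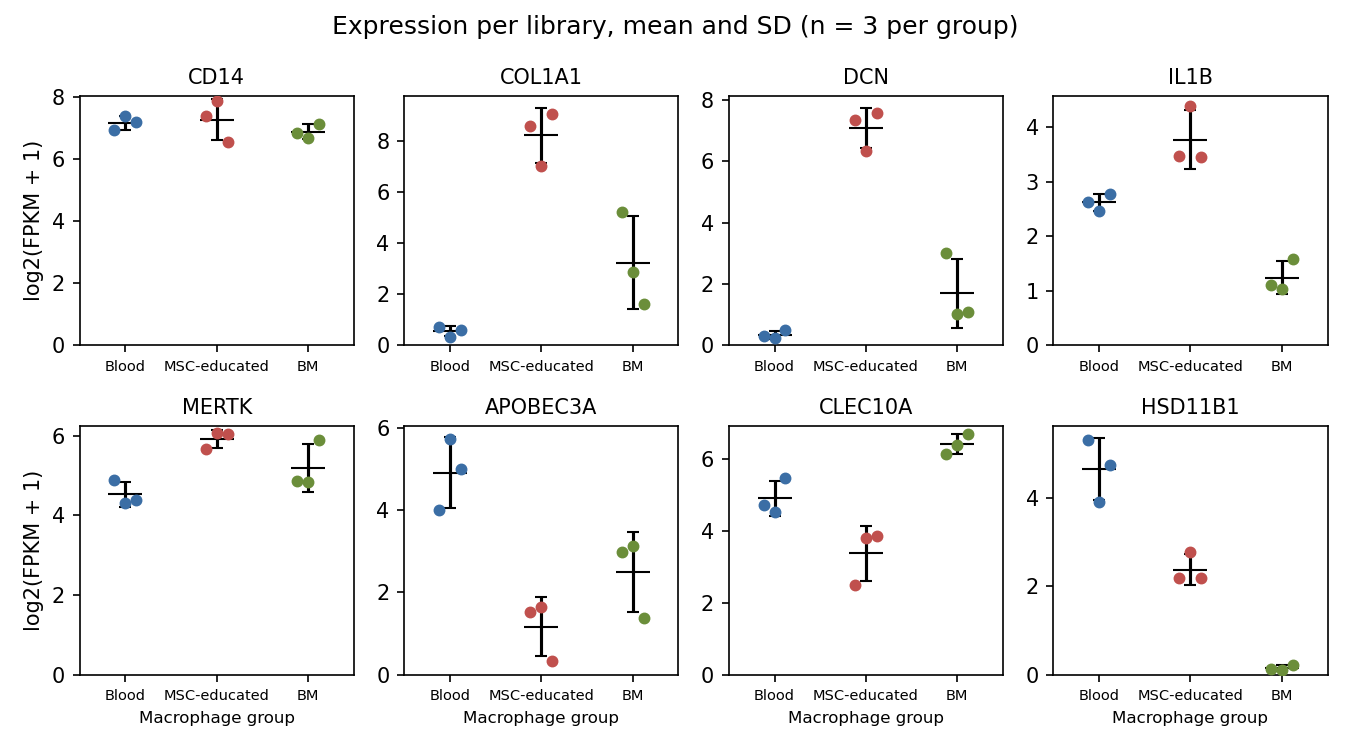
Expression (log2(FPKM + 1)) of 8 genes in each library (coloured points) of the blood, MSC-educated and BM macrophages, with the mean (wide bar) and SD (error bar) of 3 libraries. CD14 lies between 6.56 and 7.89 in all 9 libraries, COL1A1 and DCN are highest in the MSC-educated libraries, and HSD11B1 lies at 0.21 or below in the BM libraries.

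The second comparison set MSC-educated macrophages against BM macrophages, the other classical group named in the series title. MSC-educated macrophages were grown from blood cells, so this comparison mixes contact with MSCs with the tissue of origin. These cannot be told apart within it. Collagen genes were again among the largest rises. SERPINE2 was 7.72 ± 1.09 in MSC-educated and 0.99 ± 0.62 in BM macrophages (log2 fold change 6.72 ± 0.48 SE, limma adjusted p = 3.80e-04). CEMIP, which encodes a hyaluronan-binding protein, and EFEMP1, DCN, COL12A1, COL3A1 and LUM were higher by 4.50 to 5.78 (limma adjusted p = 0.00111 to 0.00706), and all 7 calls held in every fit that left out a library. COL1A2, CALD1 and COL1A1 were higher by 5.99, 5.06 and 5.00 (limma adjusted p = 0.0187, 0.0109 and 0.0263). Of the stromal markers, 16 of 26 were higher and none lower, and 24 were higher when adjusted over the list alone. The list moved up (fry p = 0.00283, adjusted p = 0.0269, median 3.49), with adjusted p = 0.303 with an estimated correlation. The BM libraries also carried stromal transcripts, with list means of 3.58, 1.38 and 0.83 in replicates 1, 2 and 3.

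COL1A1 lost its call without blood replicate 3 (limma adjusted p = 0.0528), MSC-educated replicate 1 (0.119) or 3 (0.0846) or BM replicate 2 (0.101). COL1A2 lost it without MSC-educated replicate 1 (0.0912) or 3 (0.0658) or BM replicate 2 (0.0767) or 3 (0.0511), and CALD1 without MSC-educated replicate 1 (0.0564) or BM replicate 2 (0.0519). The stromal list lost its call without blood replicate 2 (0.0655) or 3 (0.0644), MSC-educated replicate 1 (0.120) or BM replicate 2 (0.115) or 3 (0.0821).

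The list of proinflammatory cytokines moved up in MSC-educated against BM macrophages (fry p = 2.09e-04, adjusted p = 0.00397, median 0.67), with adjusted p = 0.182 with an estimated correlation. The median was 1.26 without blood replicate 2, 1.06 among protein-coding genes alone and 1.31 with a pseudocount of 0.1. IL1B (chromosome 2, 113587328 to 113594480, hg19) was 3.77 ± 0.54 against 1.24 ± 0.30 (limma adjusted p = 0.00253). IL6 was 4.13, 2.38 and 3.48 in MSC-educated replicates 1 to 3 and listed at 0.56, 0.90 and 0 in BM replicates 1 to 3 (limma adjusted p = 0.00706). These were the 2 of 7 members to pass, and 3 passed when adjusted over the list alone. RNA of MSCs was not tested as a source of IL6 here either. Both kept their calls in every left-out fit that tested them, while the list lost its call without MSC-educated replicate 1 (adjusted p = 0.120). OSM (2.68 ± 0.77 and 1.42 ± 0.42) did not pass (limma adjusted p = 0.114), but did without MSC-educated replicate 3 (0.0396) and among protein-coding genes alone (0.0489). The scavenger and phagocytic receptor list moved up too (fry p = 0.00696, adjusted p = 0.0441, median 0.92), with adjusted p = 0.303 with an estimated correlation. GAS6 was higher by 2.69 (SE 0.42, limma adjusted p = 0.00993) and MRC1 by 1.91 (SE 0.36, limma adjusted p = 0.0232), 2 of 17 tested members, and 5 were higher when adjusted over the list alone. GAS6 lost its call without MSC-educated replicate 1 (0.0578), and MRC1 without MSC-educated replicate 1 (0.103) or 2 (0.0734) or BM replicate 2 (0.0957) or 3 (0.0661). The scavenger list lost its call without blood replicate 2 or 3, MSC-educated replicate 1 or 2, or BM replicate 2 or 3 (0.0807 to 0.205). AXL, at 3.12 ± 0.68 and 1.11 ± 1.22, passed only without BM replicate 1 (limma adjusted p = 0.0848 with all libraries and 0.00510 without it), and so did NT5E (0.119 and 0.0270).

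Lower in MSC-educated than in BM macrophages were CLEC10A, a galactose-binding lectin receptor of macrophages and dendritic cells, and B lineage transcripts. CLEC10A was 3.39 ± 0.77 against 6.43 ± 0.28, with 4.91 ± 0.50 in blood macrophages (limma adjusted p = 0.00404 against BM). MS4A1, which encodes the B cell surface protein CD20, was listed at 0.47, 0 and 0 in MSC-educated replicates 1 to 3 and at 3.94, 3.74 and 2.29 in BM replicates 1 to 3 (limma adjusted p = 0.00410). It was the only B cell marker tested. Of 17 tested immunoglobulin genes, 15 were lower and none higher. Their median was 0 in the MSC-educated libraries and 0 or just above it in the blood libraries, so their low level is not particular to contact with MSCs. Genes so low elsewhere pass the expression filter only through the BM libraries, so the filter partly sets this count. AC064836.1, without a matched gene type, was lower by 3.43 (limma adjusted p = 0.00489). These 3 named calls held in every left-out fit that tested them. ORM1, an acute phase protein gene with a near-identical copy, was listed at 0.61, 0.49 and 0 in MSC-educated and at 2.65, 3.17 and 3.56 in BM macrophages (limma adjusted p = 0.0308), a call lost without any MSC-educated library or BM replicate 2 or 3 (0.0831 to 0.108). AC097532.1, AC092279.1, the ribosomal protein pseudogene RPL39P34 and a short gene at the SCARNA10 locus were also among the largest falls (limma adjusted p = 0.0162, 0.0248, 0.0242 and 0.00993). Leaving out single libraries ended these calls for AC097532.1 (MSC-educated replicate 3 or BM replicate 2 or 3, 0.0605 to 0.0698), AC092279.1 (MSC-educated or BM replicate 1 or 2, 0.0559 to 0.111), RPL39P34 (any MSC-educated or BM library, 0.0518 to 0.105) and SCARNA10 (MSC-educated replicate 1, 0.0516). Reads of pseudogenes and overlapping genes can be shared with their partners, so RPL39P34, SCARNA10 and ORM1 are uncertain.

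The other 16 tested lists gave no directional change in this comparison on the deposited scale. Members outside the fixed rule are again named after their values were seen. FOS, FOSB, EGR1 and DUSP1 were higher among 15 immediate early and stress genes (fry adjusted p = 0.152), PFKP, CA12 and ANKRD37 among 19 glycolysis and hypoxia genes (0.0763), CCL3 among 10 inflammatory chemokines (0.170) and FGF2 among 16 growth factor and repair genes (0.218). C3 and CFP were lower among 14 complement genes (0.931), and MPO was lower among 8 granulocyte markers (0.170). Among 15 alternative activation genes, MRC1 was higher and CLEC10A lower (0.298). The 18 interferon response genes had fry adjusted p = 0.680 as a list. No member passed among the macrophage identity, immune regulation, antigen presentation, matrix protease, lipid handling, cholesterol synthesis, cell cycle and osteoclast lists. Without MSC-educated replicate 3, the immediate early (adjusted p = 0.0190), glycolysis (0.0190), chemokine (0.0277), matrix protease (0.0277), complement (0.0428) and cholesterol synthesis (0.0429) lists were called. The glycolysis list was also called without BM replicate 1 (0.0400) and under each other scaling but that to the macrophage identity list (0.0124 to 0.0187). The immediate early list was called under each other scaling but quantile normalization (0.0164 to 0.0494), antigen presentation, downwards, after scaling to the macrophage identity list (0.0190) and granulocyte markers with no filter (0.0466). The macrophage identity list had a median of -0.04, a mean of 0.06 and a downward test, and lipid handling a median of -0.04, a mean of -0.18 and an upward test with fry but not camera (fry adjusted p = 0.997 and 0.951). The lowest change in the lipid list, -2.85, was that of LIPA, whose zeros can be failed estimates. LIPA was listed at 0, 9.59 and 0 in MSC-educated and at 8.69, 9.44 and 0 in BM replicates 1 to 3. Of the fixed panel, TNF (0.63 ± 0.26 in BM), IL10 (3.12 ± 0.64), TGFB1 (4.08 ± 0.24), CD163 (6.33 ± 0.17), CD274 (1.74 ± 0.14), TNFAIP6 (1.74 ± 0.19) and VEGFA (4.14 ± 0.69) did not differ by the test (limma adjusted p = 0.109 to 0.862).

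In all, 372 genes differed between MSC-educated and BM macrophages, 294 higher and 78 lower (limma, adjusted over 12918 genes), and 2229 had an unadjusted p under 0.05. At an absolute log2 fold change of 1 or more, 282 were higher and 68 lower. Groups did not overlap for 20.8% of genes, against 10% by chance. The share of higher calls was 79.0%, but 59.3% after quantile normalization (293 higher, 201 lower), 65.6% after upper-quartile scaling (273 and 143) and 68.5% after scaling to the macrophage identity list (165 and 76). With no expression filter COL1A1, MRC1, ORM1, RPL39P34, AC092279.1 and AC097532.1 lost their calls (limma adjusted p = 0.0512 to 0.0990), and after scaling to the macrophage identity list COL1A1, COL1A2, AC092279.1 and AC097532.1 did (0.0604 to 0.0796). With only the 2 groups compared COL1A1, COL1A2, CALD1 and AC092279.1 lost theirs (0.0578 to 0.0892), as did the stromal and scavenger lists (both 0.106). ORM1 lost its call with the stricter filter (0.0710) and a pseudocount of 0.1 (0.0548), and so did the scavenger list (0.125 and 0.0632). Without MSC-educated replicates 1, 2 and 3 the count was 87, 188 and 195, and without BM replicates 2 and 3 it was 124 and 137. It was 139 with no expression filter, 201 with the stricter filter, 217 with only the 2 groups compared and 241 after scaling to the macrophage identity list.

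The genes that changed the same way against both other groups numbered 201, of which 194 were higher and 7 lower in MSC-educated macrophages. They held 16 stromal markers, IL6, FGF2, GAS6 and CA12 among the higher genes. Matrix genes outside the stromal list were higher too, such as COL12A1, FBN1, COL8A1, COL4A1 and LOXL2, all but COL12A1 named after their values were seen. RNA of MSCs left after the CD14 sorts is a candidate source of such genes as well. The 7 lower genes were CFP, which encodes properdin of the complement pathway, the transcription factor gene BCL11A, ITGAL, TMEM138, CRTC3-AS1, AC064836.1 and ENSG00000256664, named after their values were seen except ITGAL and the last pair. Both comparisons used the same MSC-educated libraries. Unchanged groups simulated against shared libraries gave means of 0 higher and 0.01 lower genes (highest 0 and 1), and independent lists would share 7.97 and 0.459. The simulated groups held no change and so few calls to share. Their overlap cannot show how much of the real overlap comes from sharing libraries. The log2 fold changes correlated at 0.613 across genes, against 0.498 in the simulation, and their covariance was 0.317 against 0.0874. The 3 shared libraries could not be split into parts of 2, so part of the overlap may come from them. The count was 120 and 107 without blood replicates 2 and 3, and 33, 113 and 53 without MSC-educated replicates 1, 2 and 3. Without BM replicates 1, 2 and 3 it was 317, 77 and 84.

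The third comparison gave the difference between the classical groups. HSD11B1 (chromosome 1, 209859510 to 209908295, hg19) was 0.15 ± 0.06 in BM and 4.65 ± 0.71 in blood macrophages (log2 fold change -4.50 ± 0.33 SE, limma adjusted p = 0.00101, and -6.87 with a pseudocount of 0.1), the only named call of this comparison to hold in every left-out fit. DCSTAMP, a gene of macrophage fusion, was lower by 4.03, CHI3L1 by 3.85, the fatty acid binding protein gene FABP3 by 3.20, SCIN by 2.96 and GPAT3, an enzyme of triglyceride synthesis, by 2.86 (limma adjusted p = 0.0225, 0.0140, 0.0391, 0.0225 and 0.00652). CRABP2 was listed at 1.06, 0 and 0.79 and SLC12A8 at 0, 0.93 and 0.46 in BM replicates 1 to 3, against 3.00 to 5.10 and 2.99 to 4.50 in the blood libraries (limma adjusted p = 0.0445 and 0.0354). IL1B was lower by 1.38 (SE 0.29, limma adjusted p = 0.0470).

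Higher in BM macrophages were THBS1 (7.67 ± 1.55 against 2.76 ± 1.07, limma adjusted p = 0.0417), the transporter gene ABCB5 (3.39 ± 0.80 against 0.73 ± 0.39, 0.0175), TXNIP, a thioredoxin inhibitor (6.65 ± 0.35 against 4.71 ± 0.43, 0.0225), and SDS, the serine dehydratase gene (6.85 ± 0.51 against 5.06 ± 0.10, 0.0494). MS4A1 was listed at 3.94, 3.74 and 2.29 in the BM libraries and at 0.33, 0.09 and 0.19 in the blood libraries (limma adjusted p = 0.0108). Of 17 tested immunoglobulin genes 14 were higher, a share partly set by the expression filter, which most of them passed through the BM libraries. The noncoding genes SCARNA10, AC008738.2 and HIF1A-AS3 were also higher (limma adjusted p = 0.0263, 0.0263 and 0.0360). AC008738.2 (chromosome 19, 33790853 to 33793430) lies within CEBPA (33790840 to 33793470), which was 1.85 ± 0.80 in BM and 4.19 ± 0.08 in blood macrophages (limma adjusted p = 0.0225). Reads of such overlapping genes cannot be told apart without knowing the strand, so both values are uncertain, as are those of SCARNA10 and HIF1A-AS3.

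Of the 17 genes called under the naming rule, only 1 kept its call in every fit that left out a library. Such a fit has fewer libraries, so a lost call need not mean that a single library carried the change. FABP3, for example, had log2 fold changes of -2.97, -3.31 and -3.31 without blood replicates 1, 2 and 3. GPAT3 lost its call without BM replicate 1 (limma adjusted p = 0.0521), MS4A1 without blood replicate 2 (0.0522) and ABCB5 without blood replicate 1 (0.0586) or 2 (0.0683) or BM replicate 1 (0.0734). CHI3L1 lost it without blood replicate 1 or 2 or BM replicate 1 or 3 (0.0502 to 0.0739), and TXNIP without blood replicate 2 or 3 or BM replicate 1 or 3 (0.0760 to 0.0823). DCSTAMP, SCIN and AC008738.2 lost it without any blood library or BM replicate 1 or 3 (0.0545 to 0.0924), HIF1A-AS3 without any blood library or BM replicate 1 or 2 (0.0724 to 0.110) and SCARNA10 without any blood library (0.0760 to 0.0924). THBS1 and FABP3 lost it without any blood library, MSC-educated replicate 1 or BM replicate 1 or 3 (0.0646 to 0.125), and SLC12A8 without any blood or BM library (0.0532 to 0.101). IL1B, CRABP2 and SDS lost it without any blood or BM library or MSC-educated replicate 1 (0.0626 to 0.151). With no expression filter, only HSD11B1 and GPAT3 of the 17 genes called under the naming rule kept their calls (0.0714 to 0.163 for the others). IL1B and THBS1 also lost theirs after scaling to the macrophage identity list (0.0753 and 0.0879), THBS1 after quantile normalization (0.0502) and with only the 2 groups compared (0.0501), and CRABP2 and SDS with a pseudocount of 0.1 (0.0523 and 0.0509).

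On the deposited scale no list moved in 1 direction between BM and blood macrophages after adjustment (fry, 0 of 19 lists, with 4 at an unadjusted p under 0.05, and camera with an estimated correlation, 0 and 0). The 26 stromal markers had a median of 1.23 and none passed (fry adjusted p = 0.306). Members named next were chosen after their values were seen, except IL1B, DCSTAMP and THBS1. Of 18 interferon response genes, 7 were lower when adjusted over the list alone (fry adjusted p = 0.147). FOS and EGR2 were lower among 15 immediate early genes (fry adjusted p = 0.191, 7 lower over the list alone), IL1B among 7 proinflammatory cytokines (0.147), CCL3 among 10 chemokines (0.234) and DCSTAMP among 7 osteoclast markers (0.191). CEBPA was lower among 18 macrophage identity markers (0.453), CLEC7A among 15 alternative activation genes (0.669) and FASN among 14 lipid handling genes (0.453). No cholesterol synthesis gene passed over all genes and 10 of 18 were lower over the list alone (0.147). MPO was higher among 8 granulocyte markers (0.168), CIITA among 15 antigen presentation genes (0.994) and THBS1 among 16 growth factor and repair genes (0.226). Without MSC-educated replicate 3, the osteoclast (adjusted p = 0.00132), cytokine (0.0195), cholesterol (0.0195), interferon (0.0461) and immediate early (0.0461) lists were called, and so was CD274 as a gene (limma adjusted p = 0.0838 with all libraries and 0.0202 without it). With only the 2 groups compared, the osteoclast (0.00630), cytokine (0.0183), cholesterol (0.0356) and immediate early (0.0497) lists and CD274 (0.0350) were called. The cytokine list was also called after quantile normalization (0.0424), median-ratio scaling (0.0391) and among protein-coding genes alone (0.00611), and the cholesterol list after scaling to the macrophage identity list (0.0137). All of these called lists pointed down. Median, mean and test differed in sign for alternative activation (-0.21, -0.02, down with fry and up with camera), immune regulation (0.15, -0.19) and matrix proteases (0.18, -0.20), both likewise, complement (-0.21 and -0.10, likewise), scavenger receptors (-0.05, 0.10, up), antigen presentation (-0.03, -0.08, up) and the cell cycle (0.11 and just under 0, down with fry and up with camera).

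In all, 230 genes differed between BM and blood macrophages, 57 higher and 173 lower (limma, adjusted over 12918 genes), with 2787 at an unadjusted p under 0.05. At an absolute log2 fold change of 1 or more, 53 were higher and 163 lower, and 31.4% of genes did not overlap between groups, against 10% by chance. The split moved with the scaling, from 24.8% higher to 113 higher and 144 lower after quantile normalization, 169 and 160 after upper-quartile scaling, 133 and 208 after median-ratio scaling, 71 and 75 after scaling to the macrophage identity list, and 150 and 247 with protein-coding genes alone. The median log2 fold change of all genes was -0.12 and ran from 0.01 to 0.15 under these scalings. The count was 11 with no expression filter and 641 with only the 2 groups compared. The count was 17, 17 and 33 without blood replicates 1, 2 and 3, and 6, 72 and 13 without BM replicates 1, 2 and 3. It was 56 and 973 without MSC-educated replicates 1 and 3, which entered only the expression filter and the estimate of the spread.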

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

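The median-ratio, upper-quartile, protein-coding and macrophage-list scalings, the removal of genes with a 0 beside a high value, and the filter, pseudocount and group settings for the lists were chosen after the data were seen, and the other alternatives before. Over all alternatives, named genes were on the same side of the threshold in 1795 results, lost a call in 244 and gained one in 23, lists in 1087, 52 and 46, and counts stayed within 1.5 times in 79 and moved further in 70. No direction of a call reversed. Depth limits low genes most in the BM libraries, which were the shallowest by the crude measure. Size factors, tests and trimmed-mean scaling that need counts were not run, because the values were log2 FPKM. Where a cause is not named, the cause was not tested.

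Scaling to the macrophage identity list gave 241 genes for MSC-educated against BM macrophages, 146 for BM against blood macrophages and 107 changed the same way against both groups, with 8, 5 and 1 lists in the 3 comparisons (MSC-educated against blood, MSC-educated against BM, BM against blood). Protein-coding genes alone gave 397 genes for BM against blood macrophages, with 5 lists for MSC-educated against BM and 1 for BM against blood. Quantile normalization gave 1 list for BM against blood, upper-quartile scaling 5 for MSC-educated against BM, and median-ratio scaling 5 and 1 for these comparisons.

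Without a filter, which tests more genes, 253, 139 and 11 genes passed in the 3 comparisons, of which 216, 128 and 11 had passed with it, 89 changed the same way, and 1 list moved against blood and 6 against BM. The stricter filter gave 178 genes against blood and 201 against BM macrophages, 80 changed the same way and 1 list in each. A pseudocount of 0.1 gave 108 genes changed the same way. With only the 2 groups compared, 217 genes passed for MSC-educated against BM and 641 for BM against blood, with 1, 1 and 4 lists. Camera with an estimated correlation gave 0 lists against blood and 0 against BM, with 5 and 3 at an unadjusted p under 0.05.

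Leaving out each library gave 76 to 473 genes for MSC-educated against blood, 87 to 453 against BM, 6 to 973 for BM against blood and 33 to 317 changed the same way, with 0 to 6, 0 to 9 and 0 to 5 lists. The lowest numbers of genes were without MSC-educated replicate 1, except 6 without BM replicate 1, and 973 was without MSC-educated replicate 3. Of the named genes that passed, 15 of 29, 12 of 22 and 1 of 17 kept the call in every such fit that tested them, and of the lists 0 of 5 and 0 of 3.

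With the replicate number as a block, 423, 319 and 203 genes passed in the 3 comparisons, 183 changed the same way, and 4, 3 and 0 lists moved. Against blood macrophages GDF15 (limma adjusted p = 0.0531), NT5E (0.0522), CD274 (0.0679) and the cytokine (0.0592) and osteoclast (0.0537) lists then did not pass, and MRC1 (0.0424) and, downwards, the interferon response list (0.0410) did. IL1B (0.0611), SDS (0.0692) and CRABP2 (0.0745) did not pass for BM against blood. No other gene named under the rule, and no other list, changed its call with the block. Deviations of libraries with the same number correlated at -0.17 to 0.07 between blood and MSC-educated, -0.04 to 0.13 between MSC-educated and BM, and -0.03 to 0.02 between blood and BM libraries, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries.

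For each comparison, 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 426, 372 and 230 genes and the highest other split 4, 3 and 2, so 1 of the 10 splits gave as many in each. For the lists, the real splits gave 5, 3 and 0 and the highest others 0, 0 and 0, and with 0 lists for BM against blood all 10 splits gave as many. For the genes changed the same way, 1 of 100 splits of the 9 libraries, the real one, gave as many as 201, and the highest other gave 8. The other splits mix groups, which widens the spread within a group where the groups differ. With 10 splits, the low counts of the others cannot exclude chance in a single comparison. The 100 splits of the 9 libraries show that the 3 groups are not all alike. They do not show how much of the overlap comes from the shared MSC-educated libraries.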

Other observations

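The genes in the opening account, the weighed tests of stromal, lower and immunoglobulin genes, and the splits for numbers of genes were chosen after the results were seen. Several genes of glycolysis and oxygen sensing were higher in MSC-educated than in blood macrophages. The glucose transporter gene SLC2A1 was 3.14 ± 0.50 against 1.37 ± 0.38 (limma adjusted p = 0.0195), BNIP3, which acts in removal of mitochondria, 4.40 ± 0.31 against 2.79 ± 0.27 (0.0291), and the carbonic anhydrase gene CA12 3.45 ± 0.69 against 0.03 ± 0.04 (0.00851). CA12 was thus near the floor in blood macrophages, and RNA of MSCs was not tested as its source. Of 19 tested members of that list, 10 were higher when adjusted over the list alone, and the list had fry adjusted p = 0.0539. VSIG4, a complement receptor of tissue macrophages, was 6.96 ± 0.69 against 4.83 ± 0.71 (0.0284). CFP, the properdin gene, was lower, at 1.20 ± 0.45 against 3.33 ± 0.23 (0.00337).

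FOS, an early response transcription factor gene, was 4.40 ± 0.73 in BM, 6.75 ± 0.87 in blood and 7.60 ± 0.32 in MSC-educated macrophages (limma adjusted p = 0.0412 for BM against blood and 0.00657 for MSC-educated against BM). CCL3, a chemokine gene with near-identical copies, was 1.88 ± 0.70 in BM and 4.21 ± 0.10 in blood macrophages (0.0121). MPO, the peroxidase of granulocyte precursors, was 1.73 ± 0.15 in BM, 0.31 ± 0.17 in blood and 0.49 ± 0.35 in MSC-educated macrophages (0.0388 for BM against blood).

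Stromal markers were among the largest rises in MSC-educated macrophages, and RNA of MSCs left after the CD14 sorts is a candidate source. Of the raised genes outside the stromal list that averaged under 1 FPKM in blood macrophages, 69.2% ordered the MSC-educated libraries as the list does, against 26.1% of equally low genes that did not pass and 16.7% by chance, while raised genes at FPKM 5 or more in blood did so in 38.2%. The most abundant list members, COL1A2 and COL1A1, reached 8.72 and 8.23 on the log2 scale, 7 of the 26 members averaged FPKM 1 or more in blood macrophages and 0 are in another list. Scaling alone is excluded, because the median of the list stayed at 4.46 or more under every scaling. A response of the macrophages themselves was not tested and stays open. Stromal transcripts also reached a mean of 3.58 in BM replicate 1, for which no added MSCs are described, and 1.38 and 0.83 in BM replicates 2 and 3. MSCs can be grown from bone marrow, so these values do not decide between the sources.

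The 76 genes lower in MSC-educated than in blood macrophages could have been lowered by RNA of other cells, which would lower all macrophage genes by about as much. The 18 macrophage identity markers had a median log2 fold change of -0.33 (SD 0.66 over members) against -1.39 for the 76 genes, a gap of 1.05, and 1 marker was as low as that median. The 76 genes were picked because they fell and the markers were not, so part of this gap is built in and it cannot decide. With the libraries scaled to these markers the median of the 76 was -1.13 (median SE 0.29), and 34 still passed. These 34 therefore fell by more than the mean of the markers. The other 42 lost their calls with a smaller change (median -1.15 before and -0.95 after) and a larger SE (median 0.25 and 0.29). Dilution as the cause for those 42, or as part of the size for all 76, stays open. A response of the identity markers themselves and a response of the 76 genes to MSCs stay open too, and none of these was tested separately.

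Immunoglobulin genes were higher in BM than in blood macrophages in 14 of 17 cases, with a median of 2.25, 4.30 and 2.27 in BM replicates 1, 2 and 3. Their median was 0 or just above it in the blood and MSC-educated libraries. Genes so low there pass the filter of FPKM 1 in 3 libraries only through the BM libraries. The filter therefore partly sets the 14 of 17. RNA of B lineage cells is a candidate source that a CD14 sort would be meant to remove. Of the B cell list, 63.6% (7 of 11 members, MS4A1 among them at 3.94, 3.74 and 2.29) was higher in all 3 BM than in all 3 blood libraries, against 1 of 19 T and NK cell, 1 of 12 erythroid, 4 of 10 platelet and 7 of 16 granulocyte markers. Over all tested genes, 31.4% did not overlap between BM and blood macrophages, in either direction. In blood macrophages 0 of the 11 members averaged FPKM 1 or more, and 0 are in another list. Only 1 of the 11 passed the expression filter, so most of the 63.6% rests on low values, and the BM libraries were the shallowest by the crude measure. Scaling is excluded, because the median log2 fold change of the immunoglobulin genes stayed at 2.71 or more in the 4 scalings that keep them. Other differences between bone marrow and blood as the tissue of origin stay open and were not tested.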
